A study of Danio rerio with 20 samples.

How the data were processed

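RNA abundance was measured in whole zebrafish embryos at 24 hours post fertilisation on 20 Agilent one-colour arrays. Per the labels' protocols, plasmids were injected into 1-cell embryos, total RNA was extracted with Trizol and treated with DNase, and Cy3-labelled cRNA was made from 0.6 µg of RNA. The labels give 7 groups: wild type (2 arrays), empty plasmid (3), a plasmid with the endogenous serine tRNA gene (3, called Ser below) and plasmids with mutant serine tRNA genes labelled Ala, Gly, Val and Leu (3 each). The base changes in the mutant genes are not spelled out in the labels used here. Nor do the labels say whether the arrays of a group came from separate pools of embryos, so p-values measure only the spread between these samples, which may be technical. Each array is named by its group and its number in the labels, as in Ser 1.

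The authors deposited 1 scanner file per array, which holds spot intensity on a linear scale. Per the file headers, images were quantified with Agilent Feature Extraction 10.5.1.1, whose processed signal is an intensity after background treatment, and the header annotation dates from the Zv7 (danRer5) assembly. The authors also deposited a value table on the log2 scale. Its scale was not stated and was found by comparison: between 96.8% and 100.0% of each column lay within 0.001 of log2 of that array's processed signal, with signals under 1 raised to 1 and no scaling or centring between arrays. Column medians of that table on the log2 scale were 6.22 and 5.70 for wild type, 6.11, 6.13 and 5.62 for empty plasmid, 5.99, 5.90 and 5.42 for Ser, 6.19, 5.98 and 5.74 for Ala, 6.45, 6.15 and 5.59 for Gly, 6.55, 6.03 and 5.44 for Val, and 6.34, 6.04 and 6.01 for Leu.

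Processed signals were put on the log2 scale and each array's 75th percentile over non-control probes was subtracted. Of 45220 spots per array, 43803 were not controls and measured 43603 probes. Spots of one probe were averaged, and 82 values from spots marked as outliers were left out in 78 genes. Saturated spots were kept. Probes were kept where they were well above background on every array of at least 1 group, which left 32515 probes. Accessions were turned into gene symbols through the RefSeq gene table of the GRCz12tu assembly, used for names only: 15163 probes had a symbol, 0 had several and 28440 had none. For each gene name the probe with the highest mean signal was tested, which gave 27130 genes, 9822 of them with a symbol and 17308 known here by accession only. Of the tested genes, 4452 had more than 1 kept probe, and the other probes were used as an alternative. No genome sequence or coordinates were used here.

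Group means were fitted over all 20 arrays by least squares without a block, with code of its own that solves genes with left-out values on their remaining arrays, and variances were moderated with eBayes of limma 3.58.1 (default settings) in R 4.3.3. Run beside limma's lmFit without a block, this code gave the same p-values. Benjamini-Hochberg adjustment ran over all genes of a comparison, and an adjusted p under 0.05 was called a change. All tests were two-sided. Comparisons were empty plasmid against wild type, Ser against empty plasmid, each mutant against Ser, the mean of the 4 mutants against Ser, and an F test of any difference among the 4 mutants. Gene lists (33 lists, 1318 genes, 22 of them in more than 1 list) were fixed before the data were examined, as were the comparisons, the alternatives and the naming rule. They were tested with camera in limma, with a preset correlation of 0.01 and adjustment over the 33 lists of a comparison. The shift of a list is the median log2 difference of its measured genes. A list score is the mean over a list's genes of an array's log2 deviation from the mean of all arrays. Left-out values were filled with the group mean for lists, correlations between arrays and between mutants, principal components, the random slide block and the simulations. The gene tests with and without slide as a fixed block used no filled values. Members were also adjusted over the list alone.

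Named genes followed a rule: for each comparison, the 10 largest rises and the 10 largest falls among genes with a symbol that passed and whose groups did not overlap; where under 5 genes passed, the 10 symbols with the smallest p, given as values; and for each list up to 4 members with the smallest p. Not every gene that the rule takes is named in the text. A gene that was well above background on no array of one group has only a bound there. Its fold is given as "at least N-fold", the mean of the brighter group against the dimmer group's mean of, for each array, the higher of the probe's own signal and the lowest signal among probes well above background.

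Scan dates put the arrays on 5 slides of 4. Slide 1 held wild type 1, Ser 1, Ala 1 and Leu 1. Slide 2 held wild type 2, empty plasmid 1, Gly 1 and Val 1. Slide 3 held empty plasmid 2, Ser 2, Ala 2 and Leu 2. Slide 4 held Ala 3, Gly 2, Val 2 and Leu 3. Slide 5 held empty plasmid 3, Ser 3, Gly 3 and Val 3. Equal replicate numbers were not taken to pair the samples. Deviations from the group means correlated at 0.144 on average between equal numbers, over 0.1 in 35 of 57 pairs and as low as −0.18, while 17 of 20 arrays correlated best with their own number. Between other numbers the average was −0.070, and on the same slide it was 0.203. Equal numbers on different slides gave 0.071, and other numbers on the same slide 0.043. Number and slide overlap, so these values cannot tell a pairing by number from an effect of the slide. A fit with slide as a block had been planned as an alternative. Its counts are given as results of their own, and its genes named by the same rule, a choice made after the data were seen. Within-slide values are differences between single arrays or list scores on one slide, so they have no error of their own.

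Other alternatives were normexp background correction (offset 50) on the median signal, because the files used here lack the mean signal the plan named, quantile normalization, the median in place of the 75th percentile, the deposited value table, other probe filters, all kept probes, only the groups compared, eBayes with trend and robust, array weights, the replicate number as a block, a fold of at least 1.5, other controls, fry, an estimated correlation between genes, and leaving out each array in turn. Several more were added after the data were seen: slide as a random block (limma's duplicateCorrelation, consensus correlation 0.271), the slide block combined with other choices, leaving out slide 5, and the exact permutation of list scores. The deposited table, unscaled, moved the median log2 difference of all genes by −0.22 to 0.28, against −0.10 to 0.05 for the other scalings, so its values are read relative to that shift. List medians are given under another scaling where normexp, quantile normalization or the array median made them smaller by over 1.5 times. Why normexp shrank some was not tested.

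The fit was tested on simulated data with known changes, drawn on 27130 genes over 10 runs with slide effects. For Leu against Ser it recovered 0.149% of genes changed 1.5 times, 7.31% at 2 times and 63.3% at 4 times; with slide as a block these were 1.34%, 20.9% and 81.2%. For the mean of the mutants they were 1.34%, 26.1% and 82.9%, and with the block 3.73%, 42.5% and 90.8%. For lists, the simulated data had no slide effects and genes independent of one another. Lists shifted by 0.3 were found there in 30 of 30 cases, with 1 false call. This does not show how often lists are falsely called on the real arrays. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.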

Results

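Gene expression was measured in whole 24-hour zebrafish embryos that had received a plasmid with a serine tRNA gene, to see what a mutant tRNA that may put serine in the wrong places does to the embryo. The 20 arrays fall into 7 groups: wild type (n = 2), empty plasmid (n = 3), the endogenous serine tRNA (Ser, n = 3) and mutant serine tRNAs labelled Ala, Gly, Val and Leu (n = 3 each). Median signal per array ran from 43.2 to 94.2 and the 75th percentile from 524 to 1051, with 28998 to 33631 probes well above background. Arrays of a group correlated at 0.964 to 0.991 and all pairs of arrays at 0.958 to 0.994, so the closest pair came from different groups. Slide 5 stood apart: its 4 arrays (empty plasmid 3, Ser 3, Gly 3 and Val 3) had 28998 to 29786 probes above background against 30823 to 33631 on slides 1 to 4, and a brightest signal of 111525 to 128000 against 73102 to 89638. The leading principal component held 20.4% of the variance. Differences are log2 values ± the standard error of limma's contrast, from 3 arrays per group (2 for wild type), and this small number of arrays limits precision throughout. No list below stayed called when the correlation between its genes was estimated.

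What did injection of the empty plasmid change against wild type? Genes of the eye were lower (36 of 43 lower, 7 higher, median −1.03), among them the lens crystallins cryba1b (−2.03 ± 0.69) and cryba2a (−1.71 ± 0.63), the lens connexin gja8b (−1.79 ± 0.60) and atoh7 (−1.20 ± 0.43), which starts retinal ganglion cells. Skeletal muscle genes were lower too (46 of 57, median −0.37), with fast troponin T tnnt3a at −1.25 ± 0.41 and the calcium store protein casq1b at −1.61 ± 0.55. So were neuronal genes (53 of 63, median −0.41), with the synaptic snap25a at −0.71 ± 0.24. Genes of earlier stages were higher: 33 of 36 maternal and germ line genes (median 0.67) and 25 of 32 segmentation genes (median 0.70), such as the clock gene her1 (2.62 ± 0.85, above background on 1 of the 2 wild-type arrays) and mespaa (1.70 ± 0.58). Over its own list alone, the egg coat genes zp3a.1 (1.29 ± 0.38, adjusted p = 0.0424) and zp3a.2 (1.35 ± 0.35, adjusted p = 0.0238) and the oocyte gene btg4 (1.37 ± 0.34, adjusted p = 0.0238) passed in limma, as did plp1b of glia (−0.90 ± 0.22, adjusted p = 0.0415).

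In camera the eye, muscle, neuron, segmentation and maternal lists had adjusted p of 5.58e-11, 5.58e-11, 2.16e-10, 1.5e-08 and 1.02e-12. The calls were lost, at adjusted p = 0.212 to 0.341 with an estimated correlation. With normexp the medians were smaller except for muscle, at −0.28, −0.39, −0.27, 0.44 and 0.38, so the size of the eye shift depends on the background correction. Blocked by slide, their medians were −0.97, −0.47, −0.44, 0.73 and 0.75. Within slide 2, the only shared slide, scores differed by −1.46, −0.95, −0.64, 0.93 and 0.83. Smaller shifts were called for p53 targets (median 0.21, with the cell death gene bbc3 at 1.24 ± 0.44 and mdm2 at 0.78 ± 0.34), blood vessels (0.30, with the endothelial receptor kdr at 1.08 ± 0.37), inflammation (0.18, with fosab at 1.57 ± 0.53). The same held for yolk and liver (0.21), notochord (0.17, with noto at 0.98 ± 0.41) and glycolysis (−0.17, with gpib at −1.48 ± 0.45). Those 6 lists had adjusted p of 0.000673 to 0.0396. The same lists reached adjusted p = 0.341 to 0.767 with an estimated correlation. Blood vessels and notochord fell to 0.20 and 0.11 with normexp. The 6 medians with slide as a block were 0.25, 0.26, 0.24, 0.12, 0.30 and −0.33. Score differences within slide 2 were 0.15, 0.36, 0.46, 0.37, 0.29 and −0.65. The yolk and liver call ended with the block (adjusted p 0.244). Leaving out wild type 1 took the number of called lists from 11 to 21. No single gene passed over all genes in limma (0 of 27130, and 0 with slide as a block; 3 and 6 without wild type 1), while 1327 had an unadjusted p under 0.05 (664 higher, 663 lower) where 1356 are expected by chance. Members adjusted over the list alone numbered 7. The smallest p values among symbols belonged to the gap junction gene gjd6 (1.52 ± 0.30), bsg (1.45 ± 0.31) and the retinal receptor rorb (−1.21 ± 0.27), at an adjusted p of 0.978 in limma.

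Did extra copies of the normal serine tRNA gene alter the embryo relative to the empty plasmid? Genes of the yolk syncytial layer and liver were lower (28 of 37, median −0.62), including the endoderm regulator gata5 (−0.76 ± 0.27) and the plasma protein gene ahsg1 (−1.34 ± 0.53). Hatching gland genes were lower (9 of 12, median −0.40): the hatching enzymes he1.1 (−2.99 ± 0.73) and he1.2 (−1.59 ± 0.59) stood out, and he1.1 passed over its list alone (adjusted p = 0.00986 in limma). Among macrophage and neutrophil genes, 20 of 32 were lower (median −0.17), with the lysosomal protease ctss2.1 at −2.37 ± 0.73 and cebpa, a myeloid regulator, at −0.88 ± 0.30. Heart genes were lower as well (13 of 17, median −0.13), led by gata6 (−1.37 ± 0.50) and gata4 (−1.04 ± 0.42), and so were 23 of 32 segmentation genes (median −0.39), with mespaa at −1.31 ± 0.52. In the other direction lay genes of the eye (34 of 43 higher, median 0.43, mipa of the lens at 1.38 ± 0.67), neurons (51 of 63, median 0.32, dpysl3 of growing axons at 0.71 ± 0.23) and skeletal muscle (45 of 57, median 0.30, mylpfb at 1.06 ± 0.38, although acta1a was −0.98 ± 0.26).

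Camera gave these 8 lists adjusted p of 7.25e-07, 0.00366, 0.00645, 0.00851, 0.000518, 0.00946, 0.00175 and 0.00236. These became adjusted p = 0.399 to 0.609 with an estimated correlation. With normexp the macrophage and segmentation medians were −0.09 and −0.23. The 8 medians with slide as a block were −0.76, −0.36, −0.25, −0.10, −0.38, 0.48, 0.37 and 0.27. Within slides 3 and 5 scores differed by −0.61 and −0.94 for yolk and liver, −0.31 and −0.70 for hatching gland, −0.27 and −0.35 for macrophages, −0.15 and −0.73 for heart, 0.07 and −0.87 for segmentation, 0.05 and 0.71 for eye, 0.11 and 0.35 for neurons and 0.34 and −0.06 for muscle. Epidermis (median −0.08, foxi3b of ionocytes at −0.90 ± 0.31) and p53 targets (−0.06) were also called, with adjusted p of 0.0188 and 0.0266 and adjusted p = 0.522 with an estimated correlation. Epidermis was −0.03 with normexp. Blocked by slide, the 2 medians were −0.20 and −0.01, which ended the p53 call (adjusted p 0.0732), and epidermis scores differed by −0.22 and −0.51 within slides 3 and 5. Ribosomal protein genes were higher (69 of 72, median 0.20, adjusted p 0.00851, adjusted p = 0.982 with an estimated correlation). Of the 72, 69 were saturated on at least 1 array, and the median with slide as a block was 0.18, it was 0.01 after quantile normalization. With the deposited values, which are not scaled, it was −0.01. Saturation on all arrays held for 41 of the 72, where a change in RNA cannot show. The rise may thus come from the scaling alone. Its scores within slides 3 and 5 differed by 0.22 and −0.03. The heat shock list was not called (35 of 46 higher, median 0.21, adjusted p 0.0795), with dnajb2 at 0.79 ± 0.28 and bag3 at 0.52.

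Over all genes 0 passed in limma without a block (2 without Ser 2), with 2666 at an unadjusted p under 0.05 (1490 higher, 1176 lower), and 6 members passed when adjusted over the list alone. With slide as a block 11 genes rose and 149 fell in limma, 131 of these 160 with no overlap between groups, against 10% by chance for genes not chosen by a test. Genes that fell include he1.1 (−3.60 ± 0.66, adjusted p = 0.0403, within slides −2.40 and −4.14), ctss2.1 (−3.10 ± 0.47, adjusted p = 0.0302, within slides −2.60 and −3.76) and the ketone enzyme oxct1b (−3.18 ± 0.54). Others were the cytochrome P450 genes cyp2aa8 (−2.39 ± 0.44) and cyp2aa4 (−2.12 ± 0.30), the purine enzyme paics (−2.34 ± 0.44), the zinc exporter slc30a1b (−2.08 ± 0.36), the sterol transporter abcg4b (−2.02 ± 0.26) and cd9b, a tetraspanin (−1.94 ± 0.27, adjusted p = 0.0183, within slides −1.37 and −2.35). The 2 wild-type arrays alone differed widely in he1.1 (4.65 and 0.75), ctss2.1 (1.28 and −1.75) and cd9b (4.57 and 2.70). Wild type 2 lay within the range of the Ser arrays for all of these. The coactivator crtc1a rose (0.93 ± 0.18, adjusted p = 0.0436 in limma). Serpinb1l1, a protease inhibitor, fell at least 1.47-fold, since it was not well above background on any Ser array (adjusted p = 0.0173, but a difference of −0.01 with normexp and no block). The blocked count rested on few arrays: it was 0 without empty plasmid 1, empty plasmid 3 or Ser 3, 14 without Ser 1, 62 without Ser 2 and 346 without empty plasmid 2, and 0 without slide 5.

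**Figure D1:**
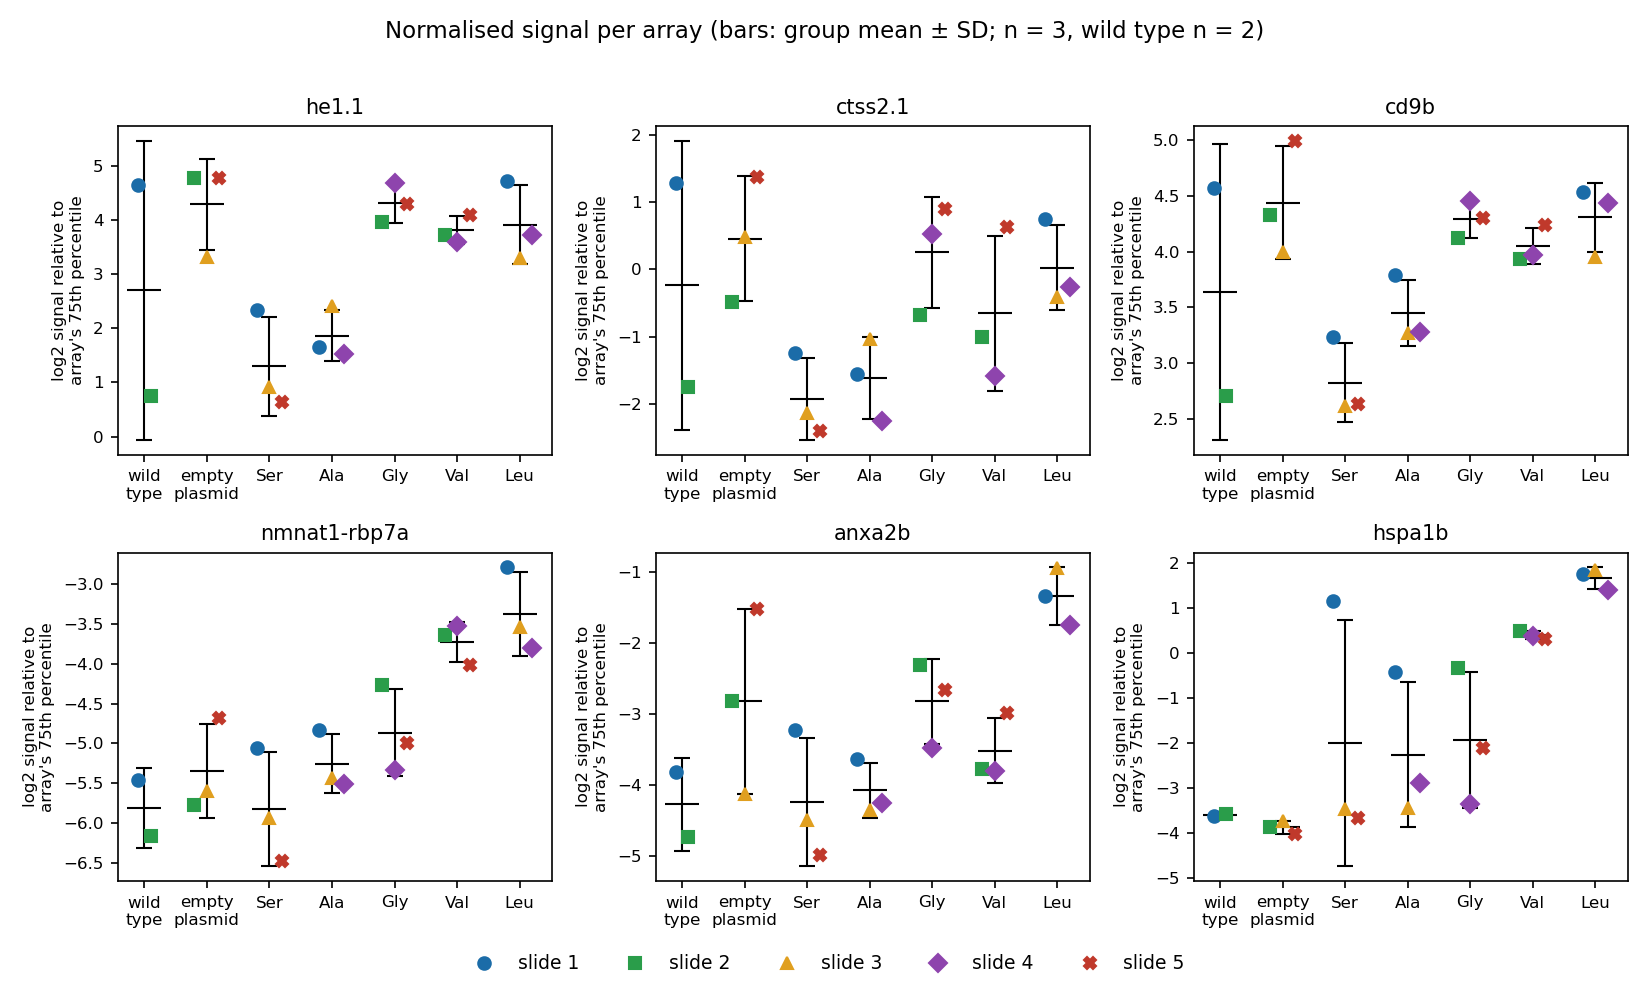
Log2 signal relative to the array's 75th percentile (y axis) of 6 genes in the 7 groups, 1 marker per array shaped by slide, with bars for group mean ± SD (n = 3, wild type n = 2). Means for he1.1 were 4.29 ± 0.84 in empty plasmid and 4.31 ± 0.37 in Gly, and for hspa1b −3.88 ± 0.15 in empty plasmid, −2.00 ± 2.74 in Ser, 0.40 ± 0.09 in Val and 1.67 ± 0.23 in Leu.

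What did the Ala mutant change relative to Ser? The differences were small. Targets of the integrated stress response, which raises amino acid supply when translation falters, were higher (24 of 32, median 0.20), with the transporters slc1a4 (1.15 ± 0.46) and slc7a3a (0.64 ± 0.31) and the kinase eif2ak1 (0.79 ± 0.33). Inflammation and immediate early genes were higher (38 of 54, median 0.18), with tlr3 (0.77 ± 0.27) and the cytokine brake socs3b (0.77 ± 0.29), and p53 and apoptosis genes slightly so (35 of 54, median 0.08, casp8 at 0.87 ± 0.29). Lower were genes of oxidative phosphorylation (54 of 69, median −0.16, ndufa7 at −0.44 ± 0.20, cox7c at −0.52 ± 0.28) and neural progenitors (40 of 49, median −0.16, the Notch ligand dla at −0.55 ± 0.25), and both medians were 0.03 with the deposited values, a turn that their shift of all genes (0.19) accounts for. Quantile normalization left oxidative phosphorylation at −0.08. The heat shock list was not called (29 of 46 lower, median −0.08, adjusted p 0.753), with unc45b, a myosin chaperone, at −0.43 ± 0.18.

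These 5 lists had adjusted p of 0.0022, 0.0022, 0.0404, 0.0213 and 0.0378 in camera. The calls were lost, at adjusted p = 0.961 with an estimated correlation. Their medians with slide as a block were 0.19, 0.23, 0.12, −0.13 and −0.11. Score differences within slides 1 and 3 were 0.35 and −0.03, 0.56 and −0.25, −0.02 and 0.05, −0.16 and −0.07, and −0.14 and 0.03. Ribosomal protein genes were lower (70 of 72, median −0.17, adjusted p 0.0022, adjusted p = 0.961 with an estimated correlation). Nearly all of them were saturated on some array, and the median with slide as a block was −0.09. With quantile normalization it was −0.01 and with the deposited, unscaled values 0.02, so the fall may come from the scaling alone. Scores within slides 1 and 3 differed by −0.35 and −0.13. The block ended the calls of neural progenitors (adjusted p 0.346) and ribosomal proteins (0.0933). The count of called lists, 6, was 0 without Ala 1 and 3 without Ser 3 or Ala 3. Not 1 gene passed in limma, with or without slide as a block, 1185 had an unadjusted p under 0.05 (511 higher, 674 lower), and 0 members passed when adjusted over the list alone. Smallest p values were those of the mannosidase man2c1 (1.23 ± 0.25), serpinb1l1 (at least 1.16-fold, but −0.08 with normexp), the deadenylase subunit pan3 (−1.76 ± 0.46), the repressor hic1 (−0.78 ± 0.21) and the Wnt scaffold axin1 (−0.77 ± 0.23, but 0.375 at another probe), all at an adjusted p of 0.941 in limma.

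How did the Gly mutant differ from Ser? Genes of the yolk syncytial layer and liver were higher (29 of 37, median 0.65), with the liver regulator hnf4a (1.88 ± 0.57), the apolipoprotein apoa1a (1.42 ± 0.47) and prothrombin f2 (1.37 ± 0.48). Hatching gland genes were higher (9 of 12, median 0.34), with he1.1 (3.02 ± 0.73, adjusted p = 0.0092 over its list alone in limma) and cd63 (0.62 ± 0.20, adjusted p = 0.0425). So were macrophage genes (23 of 32, median 0.19, or 0.07 with normexp, with the macrophage regulator irf8 at 0.70 ± 0.21 and ctss2.1 at 2.17 ± 0.73) and antioxidant genes (31 of 49, median 0.14, with nqo1 at 0.85 ± 0.30 and gstp1.2 at 0.71 ± 0.24). Neural progenitor genes were lower (45 of 49, median −0.32), with sox11a (−0.60 ± 0.18), the Notch ligand dlb (−0.65 ± 0.22) and pax6a (−0.73 ± 0.27), as were genes of neurons (51 of 63, median −0.28), with the glutamate transporter slc17a6a at −1.07 ± 0.38. The heat shock list was not called (34 of 46 lower, median −0.17, adjusted p 0.286).

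Camera gave yolk and liver, hatching gland, macrophages, antioxidant genes, neural progenitors and neurons adjusted p of 3.92e-08, 0.000875, 0.000875, 0.00353, 1.42e-05 and 0.00936. The same lists reached adjusted p = 0.224 to 0.94 with an estimated correlation. Medians with slide as a block were 0.79, 0.17, 0.25, 0.08, −0.44 and −0.25. Within slide 5, the only shared slide and the one that stood apart, scores differed by 0.82, 0.64, 0.47, 0.14, −0.55 and −0.17. Ribosomal protein genes were lower (69 of 72, median −0.25, adjusted p 3.2e-05, adjusted p = 0.94 with an estimated correlation). Nearly all of them were saturated on some array, and the median with slide as a block was −0.25. With quantile normalization it was −0.02 and with the deposited, unscaled values 0.01, so the fall may come from the scaling alone. Its score within slide 5 differed by 0.07. The 7 called lists became 11 without Ser 3, Gly 1 or Gly 2.

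Without a block 0 genes passed in limma over all genes (1 without Ser 2), 2555 had an unadjusted p under 0.05 (1189 higher, 1366 lower), and 2 members passed when adjusted over the list alone. With slide as a block 338 genes rose and 49 fell in limma, 314 of them without overlap (10% by chance for unchosen genes). Rises were he1.1 (3.57 ± 0.70, adjusted p = 0.0341, within slide 5 3.66), oxct1b (3.42 ± 0.57), ctss2.1 (3.12 ± 0.49, adjusted p = 0.0199, within slide 5 3.30) and the kinase wnk4b (2.83 ± 0.49). Further rises were protein C gene proca (2.77 ± 0.49), the glucose-releasing g6pc1a.1 (2.73 ± 0.43), carbonic anhydrase ca15c (2.70 ± 0.59) and hnf4a (2.44 ± 0.45, adjusted p = 0.0293, within slide 5 1.90). Falls were the lysosomal sulfatase gnsb (−1.65 ± 0.32), the receptor musk of nerve-muscle synapses (−1.58 ± 0.31), the deubiquitinase usp22 (−1.27 ± 0.26), pax6a (−1.11 ± 0.23), crtc1a (−0.90 ± 0.19), sox11a (−0.74 ± 0.16) and the Notch ligand dll4 (−0.70 ± 0.15). He1.1 and ctss2.1 also differed widely between the 2 wild-type arrays. Of the 149 genes lower in Ser than in empty plasmid with the block, 122 were among those higher in Gly than in Ser, a sharing that the Ser arrays favour by entering both comparisons. The 387 became 89 without Ser 1, 0 without Ser 3, 4 without Gly 1, 8 without Gly 2, 7 without Gly 3, and 0 without slide 5 or with empty plasmid as the control.

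Did the Val mutant raise stress genes relative to Ser? Genes of the endoplasmic reticulum stress response were higher (41 of 57, median 0.17), with the chaperone calr3b (1.64 ± 0.56) and dnajc3a (0.79 ± 0.34), although sec61g was −0.71 ± 0.24. Targets of the integrated stress response (22 of 32, median 0.19, cebpd at 1.21 ± 0.42, the transporter slc3a2b at 0.63 ± 0.27) were higher as well. So were proteasome subunits (31 of 41, median 0.08, the assembly chaperone psmd5 at 1.21 ± 0.45; −0.06 with the slide block) and antioxidant genes (33 of 49, median 0.19, gsto1 at 1.07 ± 0.36). The heat shock list was not called (22 higher, 24 lower, median −0.03, adjusted p 0.223). None of its genes passed over the list alone without a block: inducible hspa1b was 2.399 ± 1.02, small heat shock gene hspb1 1.01 ± 0.32 and the Hsp70 partner hspbp1 1.098 ± 0.52. Also higher were genes of macrophages (22 of 32, median 0.23, or 0.09 with normexp, havcr1 at 1.75 ± 0.40 with an adjusted p of 0.0157 over its list alone in limma), hatching gland (10 of 12, median 0.31, he1.1 at 2.51 ± 0.73), inflammation (38 of 54, median 0.11, irf7 at 0.87) and the maternal list (24 of 36, median 0.20, or 0.05 with normexp, zp3a.1 at 0.98 ± 0.34). Muscle genes were lower (40 of 57, median −0.28, troponin C tnnc2.2 at −1.001 ± 0.25, myl1 at −0.75 ± 0.24). That median was −0.10 with quantile normalization and 0.01 with the deposited values, a turn that their shift of all genes (0.28) accounts for.

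Those 9 called lists, in the order given, had adjusted p of 0.00431, 0.00655, 0.0182, 0.00435, 0.00347, 0.00471, 0.00644, 0.0189 and 0.0359 in camera. These became adjusted p = 0.387 to 0.827 with an estimated correlation. Slide-blocked medians were 0.17, 0.14, −0.06, 0.15, 0.28, 0.15, 0.16, 0.03 and −0.29. Within slide 5, the only shared slide, scores differed by 0.41, 0.32, 0.06, 0.21, 0.50, 0.59, 0.23, −0.03 and 0.20. Ribosomal protein genes were lower (70 of 72, median −0.32, adjusted p 3.22e-07, adjusted p = 0.827 with an estimated correlation). Nearly all of them were saturated on some array, and the median was −0.31 with slide as a block and −0.03 with quantile normalization. Its score within slide 5 differed by −0.07. Of the 10 calls, 6 ended with slide as a block: endoplasmic reticulum, hatching gland and inflammation (adjusted p 0.0908 each), proteasome (0.835), maternal (0.656) and muscle (0.278). The 10 called lists became 16 without Ser 3.

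Limma found 0 genes over all genes without a block (2 without Ser 1 and 1 without Ser 2), 2815 at an unadjusted p under 0.05 (1026 higher, 1789 lower), and 3 members adjusted over the list alone. Serpinb1l1, not well above background on any Ser array, came nearest (at least 2.07-fold, adjusted p = 0.0599 in limma), but differed by 0.06 with normexp. With slide as a block 48 genes rose and 6 fell in limma, 47 of them without overlap (10% by chance for unchosen genes). Rises were serpinb1l1 (the same bound, adjusted p = 0.0129), nmnat1-rbp7a (2.404 ± 0.36, adjusted p = 0.0301, within slide 5 2.47), abcg4b (1.68 ± 0.28), the lysosomal peptidase dpp7 (1.60 ± 0.23), dennd11 (1.48 ± 0.24), the lipid hydrolase abhd4 (1.40 ± 0.21), acot11a (1.31 ± 0.20) and alg2 of protein glycosylation (1.16 ± 0.17). The 54 became 14 without Ser 1, 135 without Ser 2, 0 without Ser 3, 1 without Val 1, 274 without Val 2, 0 without Val 3, 0 without slide 5 and 1 with empty plasmid as the control.

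What did the Leu mutant change relative to Ser? In the eye 38 of 43 genes were lower (median −0.86), with the lens channel mipa (−2.29 ± 0.67, adjusted p = 0.018 over its list alone in limma) and the retinal regulator vsx1 (−0.98 ± 0.27, adjusted p = 0.018), although the lens gene lgsn was higher (2.25 ± 0.50, above background on 1 of 3 Ser arrays). In skeletal muscle 47 of 57 were lower (median −0.52), with the calcium channel cacna1sb (−0.96 ± 0.22), hhatla (−1.14 ± 0.28) and fast myosin light chain mylpfb (−1.58 ± 0.38), against troponin I tnni2b.2 (1.66 ± 0.40), each at an adjusted p of 0.0094 over its list alone in limma. Genes of neurons (55 of 63, median −0.49, dpysl3 at −0.85 ± 0.23, slc32a1 of inhibitory synapses at −0.79 ± 0.23), neural progenitors (45 of 49, median −0.33, dlb at −0.87 ± 0.22, ascl1b at −0.79 ± 0.24), neural crest (24 of 32, median −0.42, tfap2e at −1.002 ± 0.31) and erythroid cells (27 of 33, median −0.26, ank1a at −1.05 ± 0.30) were lower. Maternal and germ line genes were higher (28 of 36, median 0.48, or 0.27 with normexp), with the egg coat genes zp3a.1 (1.76 ± 0.34, adjusted p = 0.00329 over its list alone in limma), zp3a.2 (1.47 ± 0.31) and zp2.3 (1.08 ± 0.28), as were segmentation genes (21 of 32, median 0.19, or 0.09 both with normexp and with the array median, wnt8a at 1.88 ± 0.48).

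**Figure D2:**
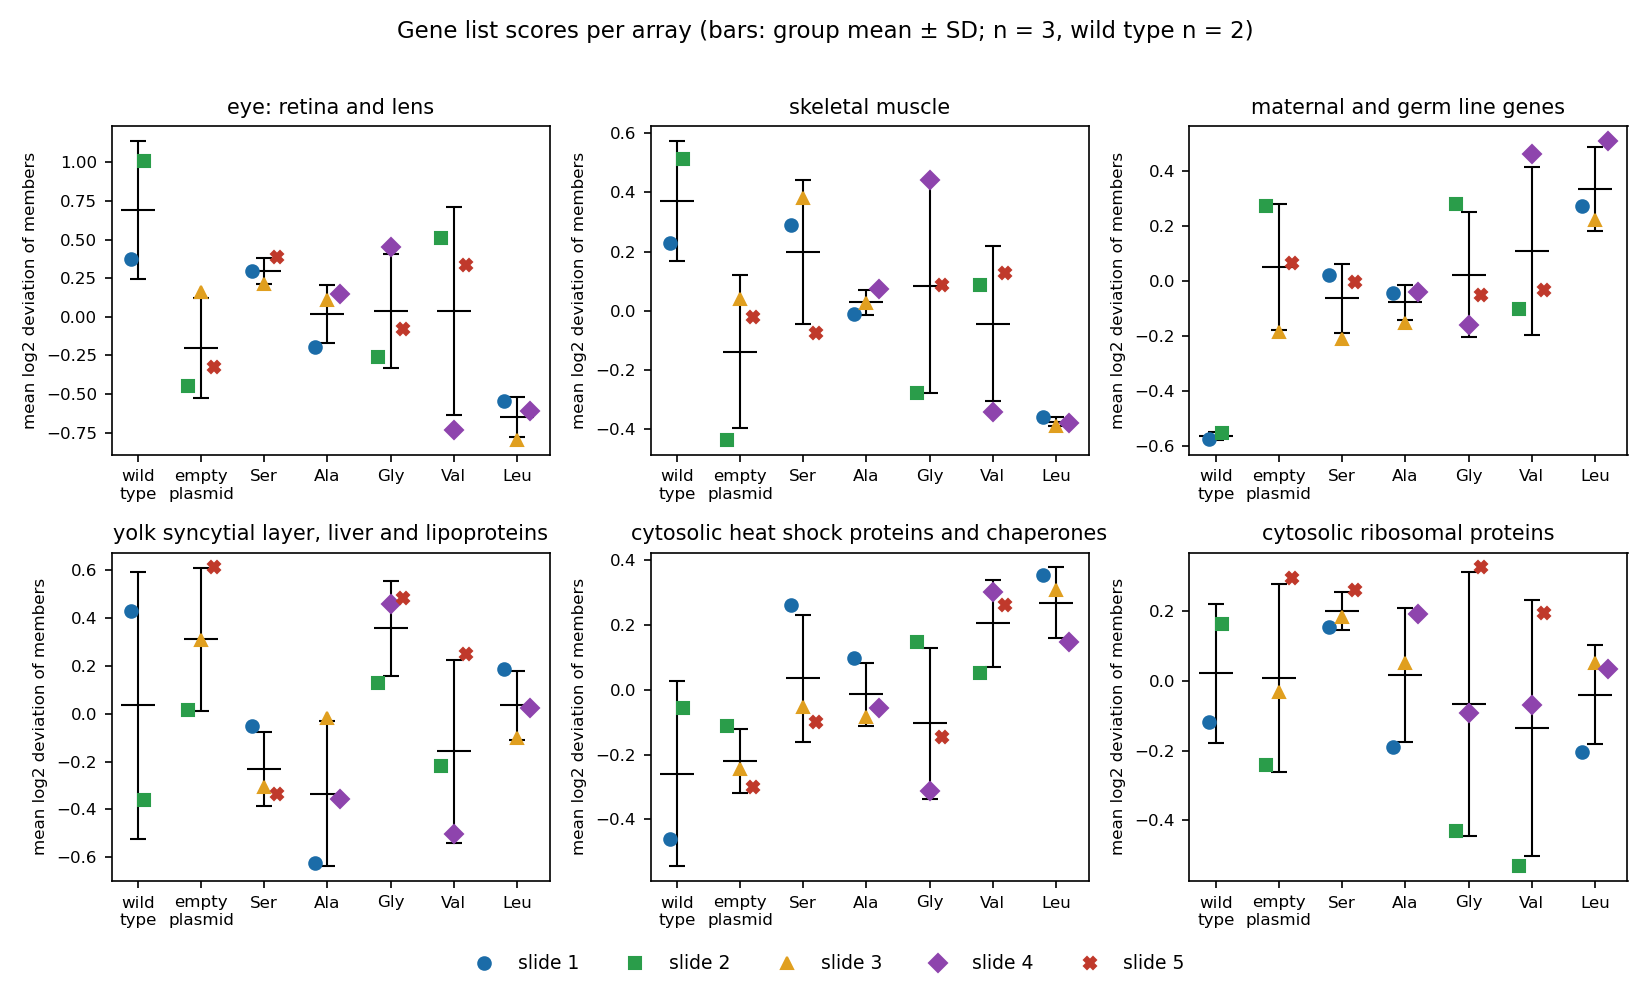
Mean log2 deviation of a list's genes (y axis) for 6 lists in the 7 groups, 1 marker per array shaped by slide, with bars for group mean ± SD (n = 3, wild type n = 2). Eye scores were 0.69 ± 0.45 in wild type, 0.30 ± 0.09 in Ser and −0.65 ± 0.13 in Leu.

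Camera gave eye, muscle, neurons, neural progenitors, neural crest, erythroid cells, maternal and segmentation lists adjusted p of 2.47e-10, 2.47e-10, 1.17e-08, 1.36e-06, 0.0111, 0.0111, 4.85e-05 and 0.0248. The calls were lost, at adjusted p = 0.364 to 0.562 with an estimated correlation. Medians with slide as a block were −0.87, −0.57, −0.51, −0.28, −0.27, −0.20, 0.38 and 0.14. Within slides 1 and 3 scores differed by −0.84 and −1.01, −0.65 and −0.77, −0.42 and −0.38, −0.32 and −0.18, −0.30 and −0.17, −0.37 and −0.03, 0.25 and 0.43, and 0.30 and 0.33. The block ended the calls of neural crest (adjusted p 0.206), erythroid cells (0.0530) and segmentation (0.0842). The 22 called lists in Leu became 12 without Ser 2 and 14 without Leu 3. In fry only the eye list (0.0493) and the autophagy list (0.0393) passed.

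Were protein stress genes higher in Leu? Of the heat shock genes, hspb1 passed over its list alone in limma (1.47 ± 0.32, adjusted p = 0.0145). Without passing, hspa1b was 3.67 ± 1.02 (adjusted p = 0.052 over its list alone in limma), hspbp1 1.78 ± 0.52 and dnajb6b 0.73 ± 0.23, and the list was not called (20 higher, 26 lower, median −0.10, adjusted p 0.433). Hspa1b was uneven between the Ser arrays, and its differences within slides 1 and 3 were 0.59 and 5.33. Genes of autophagy and ubiquitin stress were higher (23 of 33, median 0.17, or 0.06 both with normexp and with the array median), with the ubiquitin hydrolase uchl1 (1.97 ± 0.52) and the ubiquitin ligase prkn (1.54 ± 0.42) both at an adjusted p of 0.0322 over the list alone in limma. Targets of the integrated stress response were higher (23 of 32, median 0.21, slc3a2b at 1.01 ± 0.27, cebpb at 0.86 ± 0.28), as were endoplasmic reticulum chaperones (35 of 57, median 0.06, or −0.04 when scaled to the array median, which moves all genes by −0.10), with dnajb9b (2.31 ± 0.71), dnajc3a (1.07 ± 0.34) and the oxidase ero1b (0.81 ± 0.27). Cytosolic aminoacyl-tRNA synthetases were not called (6 higher, 8 lower, median −0.15, adjusted p 0.443). Genes of p53 and apoptosis (33 of 54, median 0.12, sesn3 at 1.67 ± 0.56), hatching gland (7 of 12, median 0.29, he1.1 at 2.62 ± 0.73), yolk and liver (23 of 37, median 0.15, gata5 at 0.91 ± 0.27) and inflammation (37 of 54, median 0.22, irf7 at 1.13 ± 0.48) were higher.

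Those 7 called lists (autophagy, integrated stress, endoplasmic reticulum, p53, hatching gland, yolk and liver, inflammation) had adjusted p of 0.0228, 0.00237, 0.0111, 0.0402, 0.0462, 0.0228 and 0.0302. The same lists reached adjusted p = 0.364 to 0.562 with an estimated correlation. Normexp took hatching gland to 0.16 and inflammation to 0.13. With the array median, integrated stress was 0.11, p53 0.02, hatching gland 0.19, yolk and liver 0.04 and inflammation 0.12. Medians with slide as a block were 0.15, 0.20, 0.11, 0.11, 0.33, 0.32 and 0.24. Score differences within slides 1 and 3 were 0.28 and 0.22, 0.12 and 0.35, 0.04 and 0.37, 0.15 and 0.22, 0.37 and 0.34, 0.24 and 0.20, and 0.62 and −0.07. The block ended the hatching gland call (adjusted p 0.0517).

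Housekeeping lists were lower in Leu: oxidative phosphorylation (58 of 69, median −0.29, ndufb5 at −0.44 ± 0.18, although cox4i2 was 0.95 ± 0.28), mitochondrial ribosomal proteins (52 of 57, −0.25, mrpl14 at −0.67 ± 0.28), mitochondrial chaperones (26 of 33, −0.24, phb2b at −0.71 ± 0.28). Also lower were proteasome subunits (37 of 41, −0.22, psma5 at −0.46 ± 0.26, although the inducible psme1 was 1.58 ± 0.68), cell cycle (43 of 53, −0.21, dhfr at −0.68 ± 0.30), DNA repair (47 of 59, −0.18, rad51c at −0.55 ± 0.23) and ribosomal proteins (69 of 72, −0.23, nearly all saturated on some array). They had adjusted p of 8.42e-06, 5.63e-05, 0.024, 0.0111, 0.0111, 0.0228 and 0.000122. These became adjusted p = 0.562 with an estimated correlation. Slide-blocked medians were −0.29, −0.29, −0.20, −0.19, −0.17, −0.20 and −0.15. Scores within slides 1 and 3 differed by −0.14 and −0.23, −0.09 and −0.28, −0.01 and −0.17, −0.01 and −0.13, −0.02 and −0.14, −0.02 and −0.16, and −0.36 and −0.13. With the deposited values the last 6 medians were 0.00, 0.02, 0.04, 0.05, 0.08 and 0.03, turns that their shift of all genes (0.26) accounts for. For the ribosomal list, given its saturation, the fall may instead come from the scaling alone. The ribosomal median was −0.00 after quantile normalization, which also took oxidative phosphorylation to −0.18, proteasome to −0.10 and cell cycle to −0.11. With slide as a block the call ended for mitochondrial chaperones (adjusted p 0.0519).

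Gene by gene, 0 passed in limma over all genes without a block, 3318 had an unadjusted p under 0.05 (1687 higher, 1631 lower), and 65 members passed when adjusted over the list alone. The count of 0 became 36 without Ser 1, 3 without Ser 2 and 14, all higher, with empty plasmid as the control. With array weights it was 775 (512 higher, 263 lower) and with slide as a random block 143 (113 higher, 30 lower). Smallest p values were those of nmnat1-rbp7a (2.45 ± 0.40), the growth kinase rps6kb1a (0.98 ± 0.17), the folate enzyme ggh (1.04 ± 0.19), the kinesin light chain klc3 (−1.22 ± 0.22), the methyltransferase tpmt.1 (1.67 ± 0.30) and the membrane-binding anxa2b (2.90 ± 0.56), all at an adjusted p of 0.120 in limma. With slide as a block 77 genes rose and 5 fell in limma, 78 of the 82 without overlap (10% by chance for unchosen genes). Rises were the ammonia channel rh50 (3.55 ± 0.63, within slides 2.09 and 5.64), anxa2b (3.16 ± 0.54, within slides 1.89 and 3.56), wnk4b (2.53 ± 0.46), nmnat1-rbp7a (2.48 ± 0.34, within slides 2.27 and 2.401), biotinidase btd (2.35 ± 0.38), uchl1 (2.05 ± 0.38), slc30a1b (2.02 ± 0.36), tpmt.1 (1.78 ± 0.23), the protease inhibitor cst3 (1.74 ± 0.28) and tnni2b.2 (1.72 ± 0.28). Falls were klc3 (−1.24 ± 0.21) and the phosphatase dusp23b (−1.13 ± 0.19), and hspb1 rose (1.65 ± 0.26, adjusted p = 0.0389). The 82 became 19 without Ser 1, 0 without Ser 2 or Ser 3, 4 without Leu 1, 0 without Leu 2 or Leu 3, and 0 with empty plasmid as the control.

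How did the mean of the 4 mutants differ from Ser? The mean does not show a change in each mutant: the eye list was called in Leu alone among single mutants, and muscle in Val and Leu. In the mean, lower values were seen for genes of the eye (36 of 43, median −0.48, the eye field gene six6b at −0.59 ± 0.21), skeletal muscle (44 of 57, −0.29, myl1 at −0.63 ± 0.19), neurons (49 of 63, −0.28, neff1 at −0.62 ± 0.21), neural progenitors (44 of 49, −0.26, dlb at −0.54 ± 0.17) and oxidative phosphorylation (56 of 69, −0.17, or 0.09 with the deposited values, which move all genes by 0.25). Higher were targets of the integrated stress response (23 of 32, 0.09, cebpd at 1.04 ± 0.33), endoplasmic reticulum chaperones (0.07, calr3b at 1.36 ± 0.44), antioxidant genes (0.08, mgst1.1 at 0.80 ± 0.25), p53 targets (0.05, bcl2l1 at 0.47 ± 0.15). The same direction was seen for hatching gland (10 of 12, 0.19, he1.1 at 2.18 ± 0.58), yolk and liver (24 of 37, 0.18, hnf4a at 1.52 ± 0.45), macrophages (22 of 32, 0.10, havcr1 at 1.19 ± 0.32), inflammation (41 of 54, 0.17) and the maternal list (25 of 36, 0.21, zp3a.1 at 1.07 ± 0.27). The heat shock list was not called (18 higher, 28 lower, median −0.08, adjusted p 0.893).

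With normexp the eye median was −0.30, macrophages 0.01, inflammation 0.08 and the maternal list 0.05, so the macrophage and maternal shifts all but vanish there. Quantile normalization left muscle at −0.19 and oxidative phosphorylation at −0.07. Scaled to the array median, endoplasmic reticulum was 0.04 and p53 0.03. These 14 lists had adjusted p of 0.000521, 0.000614, 0.00183, 0.000153, 0.0346, 0.00754, 0.0406, 0.0346, 0.0346, 0.0111, 0.0162, 0.0145, 0.00762 and 0.0145 in camera. The calls were lost, at adjusted p = 0.421 to 0.785 with an estimated correlation. Medians with slide as a block were −0.52, −0.24, −0.23, −0.33, −0.21, 0.06, 0.02, 0.05, 0.04, 0.16, 0.24, 0.14, 0.20 and 0.13. Within slides 1, 3 and 5 scores differed by −0.67, −0.56 and −0.26 for eye, −0.48, −0.56 and 0.18 for muscle, −0.23, −0.07 and −0.49 for neural progenitors, 0.23, 0.16 and 0.25 for integrated stress and −0.17, 0.24 and 0.70 for yolk and liver. Ribosomal protein genes were lower (70 of 72, −0.24, adjusted p 2.96e-06, adjusted p = 0.698 with an estimated correlation). Nearly all of them were saturated on some array, and the median with slide as a block was −0.20 and that with quantile normalization −0.01. The block ended the calls of endoplasmic reticulum and p53 (adjusted p 0.164 each), hatching gland (0.0533) and the maternal list (0.332). The 15 called lists became 7 without Ser 2. Permuting the list scores exactly over 12 mutant and 3 Ser arrays left none (smallest adjusted p 0.326).

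In limma 0 genes passed over all genes (1 without Ser 1 and 2 without Ser 2), 3249 had an unadjusted p under 0.05 (1518 higher, 1731 lower), and 3 members passed when adjusted over the list alone (he1.1, zp3a.1 and zp3a.2). With slide as a block 378 rose and 72 fell in limma, 57 of the 450 without overlap between all 12 mutant and 3 Ser arrays (under 1% by chance for unchosen genes). Rises were hnf4a (1.87 ± 0.34, within slides 1.45, 1.61 and 1.76), serpinb1l1 (at least 1.49-fold, but 0.00 with normexp and no block), nmnat1-rbp7a (1.69), cebpd (1.35 ± 0.24), cd9b (1.33 ± 0.22), man2c1 (1.23, but −0.02 with normexp and no block), the homeobox gene hopx (1.19 ± 0.21) and ggh (0.91 ± 0.13). Falls were taf3 of the transcription machinery (−0.98 ± 0.19), klc3 (−0.94) and hic1 (−0.84). Of the genes lower in Ser than in empty plasmid with the block, 130 were among those higher in the mutants, where the same Ser arrays again enter both sides. The 450 became 12 without Ser 1, 267 without Ser 2, 0 without Ser 3, 102, 46 and 60 without Ala 1, 2 and 3, 65, 228 and 52 without Gly 1, 2 and 3, 90 and 47 without Val 1 and 3, 40 and 285 without Leu 2 and 3, 0 without slide 5 and 0 with empty plasmid as the control.

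**Figure D3:**
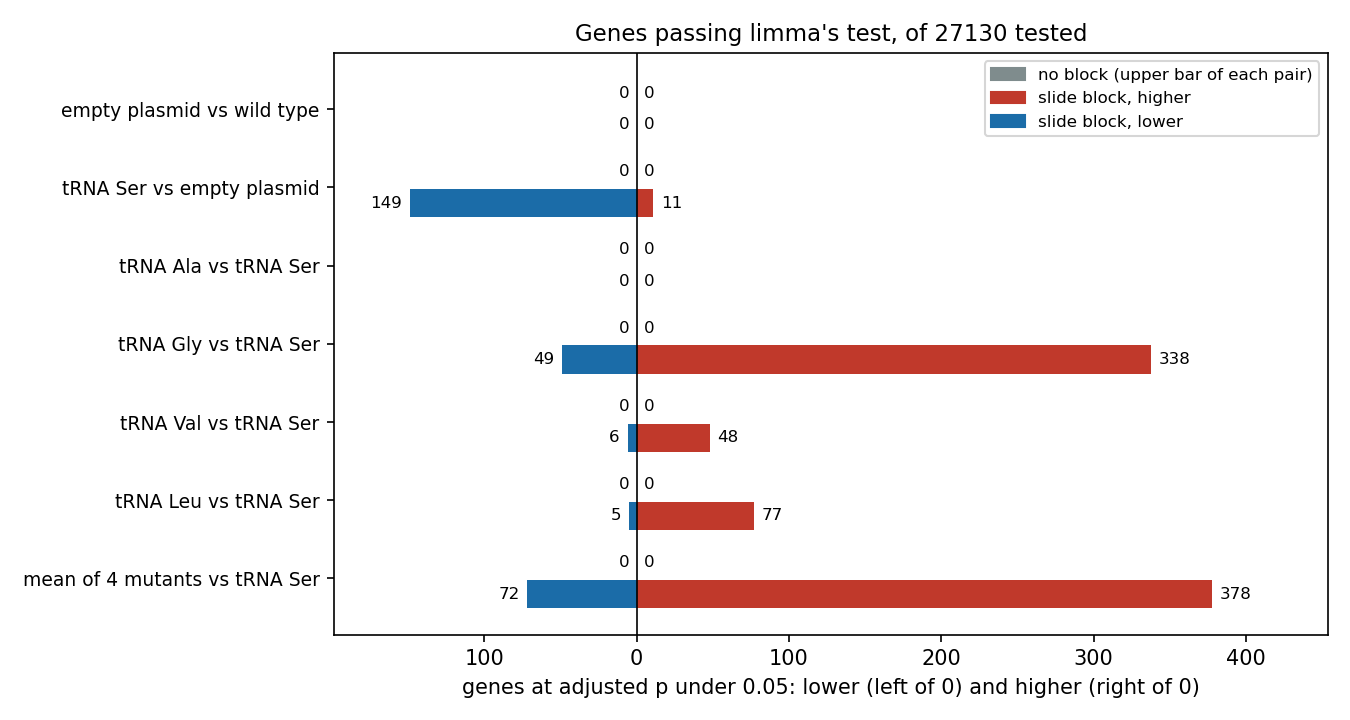
Number of genes at an adjusted p under 0.05 (axis), lower and higher, for each comparison without a block and with slide as a block. The fit without a block gave 0 in every comparison, and the blocked one gave 160 for Ser against empty plasmid, 387 for Gly, 54 for Val and 82 for Leu.

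Did the mutants differ from one another? The lens gene lgsn was high in Val (−4.40) and Leu (−4.52) and low in Ala and Gly (both −6.95, above background on 2 and 1 of 3 arrays). Tpmt.1 was −1.004 in Ala, −0.42 in Gly, −0.07 in Val and 1.02 in Leu, and the lipid gene tm6sf2b was −1.19 in Ala and 0.86 in Leu. None of these passed the F test in limma, which gave 0 genes over all genes without a block (smallest adjusted p 0.154, and 0.241 among symbols) and with it (0.112), with 1174 at an unadjusted p under 0.05, and no list score passed its F test (smallest adjusted p 0.326). Tested pair by pair in limma, 1 gene without a symbol was higher in Leu than in Ala without a block (adjusted p = 0.0294). With the block 8 genes were, among them tpmt.1 (2.02 ± 0.22, adjusted p = 0.0231 in limma), uchl1, abhd4 and zpd. In Gly, 2 genes without a symbol were higher than in Ala with the block (adjusted p = 0.0362 in limma).

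Were the mutants' changes alike? Across genes, differences from Ser correlated between mutants at 0.505 (Ala and Gly), 0.549 (Ala and Val), 0.609 (Ala and Leu), 0.732 (Gly and Val), 0.654 (Gly and Leu) and 0.601 (Val and Leu). Groups simulated without any change but with the same 3 Ser arrays as control correlated at 0.473, 0.481, 0.477, 0.503, 0.493 and 0.489 on average, so much of the likeness comes with the shared control. When 1 mutant of a pair was compared with empty plasmid instead, correlations lay between −0.318 and 0.129. Each of these correlations and covariances lay inside its simulated range, the central 95% of 200 simulations. So none went beyond what unchanged groups with a shared control of 3 arrays gave. The shuffle did not keep arrays on their slides. Gly and Val shared slides 2, 4 and 5, and Ala and Leu slides 1, 3 and 4. Likeness that comes with shared slides is therefore not in these simulations. In the slide-blocked fit the correlations lay inside as well. Covariances of Gly and Val (0.262), Gly and Leu (0.211) and Val and Leu (0.213) lay above that range. Its upper ends were 0.232, 0.196 and 0.180, which are not the highest simulated values, so some unchanged simulations lay above them too. Among slide-blocked rises, Gly and Val shared 44, Gly and Leu 39 and Val and Leu 24, a sharing that the Ser arrays enter on both sides. In 30 simulations without any change these pairs shared 0. Gly and Val had no calls there at all, so the simulations do not show how far the shared arrays alone would carry such a sharing. The same goes for genes lower in Ser than in empty plasmid. Slide-blocked covariances of Ser against empty plasmid with Gly (−0.224), Val (−0.1980) and Leu (−0.1971) against Ser lay below their simulated ranges. The lower ends were −0.206, −0.1975 and −0.1951. The covariance with Ala (−0.129) lay inside. Genes are not independent of one another, and 3 control arrays are too few to give each mutant its own.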

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

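The reported counts of changed genes without a block were all 0, and under other settings 160 counts stayed at 0 and 32 did not. Of the slide-blocked counts, 32 stayed equal to the reported value or within 1.5 times of it and 51 did not. For the number of called lists these were 85 and 41. The slide-blocked counts under other choices, the random slide block, leaving out slide 5 and the plasmid control for lists were chosen after seeing the data. Where a count moved, the cause was not tested. Genes past the threshold without a block went from 0 to 160 (Ser against plasmid), 387 (Gly), 54 (Val), 82 (Leu) and 450 (mean of mutants) with slide as a block, and stayed at 0 in every comparison with the replicate number as a block, that is, with a pairing by number. Quantile normalization gave 1 for Val, 3 for Leu, 3 for the mean and 2 for the F test among mutants; the array median 1 for Val and 2 for the mean; only the groups compared 2 for Leu and 2 for the F test. Array weights gave 2 for Val, 775 for Leu (512 higher, 263 lower), 4 for the mean and 30 for the F test, and a random slide block 2, 143 (113 higher, 30 lower), 8 and 7. For Leu, empty plasmid as control gave 14 and both controls 14. Leaving out each array in turn gave 0 to 3 genes (plasmid against wild type), 0 to 2 (Ser), 0 to 0 (Ala), 0 to 1 (Gly), 0 to 2 (Val), 0 to 36 (Leu), 0 to 2 (mean) and 0 to 0 (F test). Slide-blocked counts with quantile normalization were 245 (Ser against plasmid), 136 (Val), 142 (Leu) and 1 (F test). Without slide 5 they were 0 for Ser against plasmid, Gly, Val, Leu and the mean. With empty plasmid as control they were 0, 1, 0 and 0 for Gly, Val, Leu and the mean. Leaving out each array gave slide-blocked counts of 0 to 6 (plasmid against wild type), 0 to 346 (Ser), 0 to 351 (Gly), 0 to 274 (Val), 0 to 19 (Leu), 0 to 577 (mean, highest without Leu 1) and 0 to 4 (F test). Called lists were 0 in every comparison with an estimated correlation, with or without the slide block, and 0 with fry except 2 for Leu. For Ala they were 2 with quantile normalization, 3 with the array median and 12 against empty plasmid; for Gly 11 with the deposited values and 11 with the slide block; for Val 17 with normexp, 5 with the slide block and 16 without slide 5; for the mean 0 by exact permutation. Leaving out each array gave 11 to 21 lists (plasmid against wild type), 10 to 14 (Ser), 0 to 7 (Ala), 6 to 11 (Gly), 8 to 16 (Val), 12 to 22 (Leu) and 7 to 16 (mean). Correlations between mutants with the second or the first mutant set against empty plasmid were −0.108 and −0.318 (Ala and Gly), −0.0199 and −0.155 (Ala and Val), 0.113 and −0.0956 (Ala and Leu), 0.0172 and 0.129 (Gly and Val), 0.00161 and 0.0229 (Gly and Leu) and 0.0508 and −0.0164 (Val and Leu): the sign turns come with the loss of the shared control arrays, and for these the cause was not tested further. Among named genes 255 values stayed, 36 became past the threshold and 5 reversed. With normexp man2c1 was 0.0165 in Ser against plasmid and −0.0210 in the mean, and serpinb1l1 was −0.0750 in Ala and −0.0912 in Leu, and another probe of axin1 was 0.375 in Ala; the cause was not tested. Of 43603 probes, 11088 were not well above background in any whole group and were not tested.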

Other observations

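Tests chosen only after the result was seen were those of the slide and of the Ser control for the Leu pattern, both tests of the Ser group standing apart, and the values against empty plasmid given for single genes.

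Genes of eye, muscle and neurons were lower in Leu than in Ser and maternal genes higher, the order of such genes in a younger embryo. These are 4 of the 22 lists called in Leu. Neural progenitor, cell cycle and DNA repair genes were lower too, and whether these follow stage was not tested. The slide is argued against as the whole cause, since the smallest ratio of slide-blocked to unblocked median was 0.787. The Ser arrays are argued against as the sole source for eye, muscle and maternal lists, with a smallest ratio against empty plasmid of 0.582, but not for neurons (0.282). Part of the shift may still come from the Ser arrays, and these ratios have no error of their own. Pools of embryos that differ in stage whatever DNA they received remain open: with group means removed, eye and muscle scores correlated over the 20 arrays at r = 0.727 (Spearman 0.761, 0.689 without the 2 farthest arrays), and eye and maternal scores at −0.732. Empty plasmid against wild type showed the same 4 lists shifted the same way. Sizes depend on the background correction: with normexp the Leu medians of eye, muscle, neurons and maternal genes were −0.59, −0.41, −0.40 and 0.27. A delay caused by the Leu tRNA may add to this and is an untested hypothesis.

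Genes that rose in the mean of the mutants against Ser with slide as a block (378) may mark the Ser arrays as apart from empty plasmid, though not always alone, since Ala lay near Ser in ctss2.1 (−1.61 against −1.92) and in hatching gland scores (−0.28 against −0.32): their median was 1.06 against Ser, −0.10 against empty plasmid (ratio −0.0906) and 0.39 against wild type, although choosing genes for low values in the Ser arrays favours such a result. On 378 genes chosen without it, a left-out Ser array still lay below the empty plasmid array of its slide, relative to all genes, by 0.517 (Ser 2) and 1.16 (Ser 3) times the difference between the mutants and the other Ser arrays. A single Ser array stays open: leaving out one kept at least 0.810 of the median, but on genes chosen with all 3, and 12, 267 and 0 genes passed without Ser 1, 2 and 3. In 100 splits of the mutant and Ser arrays only the real one (1) reached 450 genes, the highest other being 125. The splits moved arrays freely between slides, while the blocked fit compares within slides, so they cannot exclude chance for that count. An effect of extra normal serine tRNA on these genes stays an untested hypothesis, as does a difference between pools.

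Ribosomal protein genes were lower in the mutants than in Ser. Lists of equally bright probes fell about as much. The list median (−0.243) lay at percentile 7.39 of 10000 lists matched on signal (median −0.235, lowest −0.268). Of the 72 members, 41 were saturated on all arrays, where a change in RNA cannot show. Probe brightness is thus enough to give a fall of this size, which was not shown to be particular to ribosomal genes. Variation of the whole list between arrays remains open as a further source (exact permutation p = 0.108). No biological explanation was tested.

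Splits of 3 against 3 arrays number 10, too few for a share under 0.05. Counts at an unadjusted p under 0.05, with the highest other split, were 2666 and 3993 for Ser against plasmid (2 splits as large, the real one included), 1185 and 2650 for Ala (5), 2555 and 2876 for Gly (2), 2815 and 3149 for Val (3) and 3318 and 1638 for Leu (1). Called lists were 11 and 14 for Ser (4 splits), 6 and 8 for Ala (5), 7 and 14 for Gly (8), 10 and 16 for Val (7) and 22 and 19 for Leu (1). The median over the other splits was 10 lists for Ser, 5 for Ala, 10 for Gly, 13 for Val and 8 for Leu. Slide-blocked genes were 160 and 0 for Ser, 387 and 1 for Gly, 54 and 0 for Val and 82 and 0 for Leu (1 split each). Of 30 simulations without any change, 1 gave 721 slide-blocked genes for Leu and the others 0, and for Ser, Gly and Val the highest was 0. For Ala 1 simulation gave 737, and for empty plasmid against wild type 2 gave calls, up to 3283. For the mean of the mutants chance is not excluded, with 3249 genes against a highest other of 4482 (5 of 100 splits) and 15 lists against 18 (11 of 100), nor for differences among mutants, with 1174 against 1948 (18 of 100). Some splits called more than the real one, so the arrays hold structure other than the groups.

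Against empty plasmid, a control planned for gene counts only, 14 genes rose in Leu and 0 fell in limma without a block, and none passed with it. Among the risers cbx7a was 3.08 ± 0.46 (8.47-fold, adjusted p = 0.0327) and tpmt.1 1.95 (adjusted p = 0.0333 in limma), chosen here after their values were seen. Heat shock genes stood higher against this control: hspa1b was 5.55 ± 1.02 in Leu (46.9-fold, adjusted p = 0.0588 over all genes and 0.00239 over the list alone in limma) and 4.28 ± 1.02 in Val (19.4-fold, 0.0308 over the list alone), and hsp90aa1.2 was 3.32 in Leu (0.00595 over the list alone). The chaperone hsp90b1 was 1.57 ± 0.35 in Val (0.0187 over the list alone) and 1.68 in Leu (0.00981). As lists, heat shock genes were called in Val (34 of 46 higher, median 0.17, adjusted p 9.79e-05, adjusted p = 0.428 with an estimated correlation) and Leu (26 of 46, 0.07, adjusted p 0.00219, adjusted p = 0.389 with an estimated correlation). In Ser against the same control the list was not called, yet more of its genes were higher and its median was larger. Mean scores of the list were −0.22 in empty plasmid, 0.04 in Ser, −0.01 in Ala, −0.10 in Gly, 0.21 in Val and 0.27 in Leu. Integrated stress targets were called in Val (0.37), Leu (0.33) and the mean (0.26), with adjusted p = 0.428, 0.389 and 0.349 with an estimated correlation. The Ser array Ser 1 was high for hspa1b (1.17), which widens the spread of the Ser group. Ser 1 was not alone in this. Ala 1 was at −0.42 against −3.46 and −2.90 in Ala 2 and 3, and Gly 1 at −0.34 against −3.35 and −2.10 in Gly 2 and 3.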
